A study of Mus musculus with 6 samples.

How the data were processed

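Total RNA from lung homogenates of 6 mice, 3 uninfected and 3 infected, was amplified to labelled cRNA and hybridised to Illumina mouse bead arrays, 1 array per mouse, per the labels' protocols. The labels call the mice separate individuals, so the spread between replicates holds spread between animals together with that between arrays and slides. The submitters' processing notes list GenomeStudio 1.1.1; its settings are not given in the sources used here. The non-normalised table deposited by the authors holds 1 signal intensity per probe and array on a linear scale. Its lowest values per array were 50.4 to 59.5, so no background had been subtracted. The second set of columns is headed as a detection p-value per the file headers, but the deposited values rise with the signal (rank correlation 0.949 to 0.982 across probes); they were therefore read as a score equal to 1 minus the detection p. The authors also deposited a table of log2 values without stated scale or centring. Set against the signals, it equalled the log2 signal minus the array median minus the median of the 3 uninfected samples for each probe, with a largest difference of 2.93e-06 over 45281 probes. Its column medians were 0 in the uninfected samples and -0.02, -0.01 and 0.04 in infected replicates 1, 2 and 3. It served as an alternative. No 2 arrays held identical signals.

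Samples were grouped by the infection label. Sample titles and descriptions give 3 days of infection, whereas the design text of the series prints both units, days and weeks; the sample labels were followed, and the conflict was not resolved. The signals were background-corrected and quantile-normalised with limma 3.58.1 in R 4.3.3 (neqc with the detection p, offset 16), giving log2 intensities. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 23371 of 45281. Platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378; the gene ID of 34807 single-symbol probes was found in the RefSeq gene table of the assembly GRCm38.p6, which was used for names and for the order of neighbouring genes and for no coordinates. Each gene was represented by its kept probe with the highest mean log2 intensity, and probes with no or several symbols stood as features of their own, which gave 15713 features, 11949 of them named genes. The second probes of Clca1, Ccl7 and Timp1 passed as well, while those of Aldh1a3 (log2 change 2.06), Ccl11 (1.84) and Fxyd4 (1.30) had smaller changes with adjusted p = 0.0803, 0.0803 and 0.0506 when all probes were tested. Il1rl1, Mki67 and Hbb-b1 were not analysed here, and neither were the list members without a probe of that name or above the filter.

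Infected and uninfected lungs were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are infected minus uninfected with their moderated SE, and fold changes carry 95% intervals. A gene not above background on any array of a group has only a bound there: the brighter group's mean was set against the mean over the dim group's arrays of the higher of the lowest signal above background and the probe's own value, and written as at least N-fold. Such a bound covers the limit of detection alone and not the spread between animals and arrays. The 95% lower limit of the fitted fold lay below the bound for each of the 5 passing genes concerned. Lists of genes, 43 in number (13 of biological processes, 11 of other tissues, handling, clock and stress, and 19 of cell types), were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 lists with at least 3 measured members. The list of liver genes had fewer and was not tested. The lists were chosen knowing that the series title names type-2 inflammation, so the type-2 lists were not chosen blind to it. Camera with an estimated correlation and fry stood beside the preset test. The estimate lay below the preset for some lists, such as cell cycle (-0.02) and complement (-0.04). A higher adjusted p with an estimated correlation therefore does not by itself show that list members were correlated. In all 17 lists passed, 16 higher and 1 lower, of which 9 were biological, 4 technical and 4 cell type lists. Of the 42 lists, 1 passed with an estimated correlation, 1 in fry's directional test and 12 in fry's test of change in either direction. These 12 included the oxidative stress list and the monocyte and interstitial macrophage list, which were not among the 17. Some lists share members, such as Lcn2 and Mt2.

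Genes were named in the text by a rule fixed before the data were examined. It took the 15 largest increases and decreases past the threshold with groups that did not overlap, or, where fewer than 10 passed, the 10 smallest p of that direction. It also took up to 4 passing members of each list, or the 2 smallest p where under 2 passed, and a fixed set of 25 genes of type-2 and other inflammation, lung cells and reference genes.

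The replicate numbers in the labels are shared between the groups. Across features, the deviations from the group means of same-numbered samples correlated at 0.21, 0.18 and 0.30 for numbers 1, 2 and 3, each above 0.1. The numbers were therefore treated as a possible pairing, on the evidence of the data alone, since the labels state none. Replicate 3 of both groups also shared slide 2, and uninfected replicate 2 correlated more with infected replicate 1 (0.24) than with infected replicate 2. All pairs on different slides correlated below 0, so these values cannot tell a pairing from a shared slide. The main fit used no pairing. Both slides held both groups, so results are also given with slide as a block and within each slide; slide 2 held 1 array of each group and gives a difference without a test.

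The steps were tested on simulated arrays built from the uninfected means and the fitted spread of each gene. Of 15638 features in the simulated comparison, a random set of genes was changed: of those kept, 22.1% of 68 with a log2 change of 1 in either direction, 93.9% of 66 with a change of 2 and 96.8% of 63 with a change of 3 were recovered, with 4 false calls. Without changes 0 features and 0 of 42 lists passed. The simulated noise was drawn independently for each gene, without slide or shared expression. The 0 of 42 lists therefore does not measure false calls on real arrays, where list members correlated (estimated at 0.39 for the inflammatory list). Splits of the real samples that mixed the groups passed up to 5 biological, 3 technical and 5 cell type lists. Alternatives covered the background correction, its offset, the normalisation, the deposited log2 table, the detection filter, the choice of probe, the variance model, array quality weights, a plain two-sample test, the replicate block, each left-out sample and, added after seeing the data, slide as a block and slide 1 alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.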

Results

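Gene expression was measured in whole-lung homogenates of 6-week-old female C57BL/6 mice, an inbred laboratory strain. One group of 3 mice was uninfected, and the other group of 3 was sampled, by the sample labels, 3 days after exposure to 500 cercariae of *Schistosoma japonicum*. Cercariae are the skin-penetrating larvae of this blood fluke, and the young worms pass through the lung on their way to the liver. The series compared the groups to describe the response of the lung to the migrating larvae. Each mouse had 1 Illumina bead array with 45281 probes, of which 47.4 to 52.0% were above background on a given array. The mean signal per array was 436, 431 and 782 in uninfected replicates 1, 2 and 3, and 434, 474 and 568 in infected replicates 1, 2 and 3. The arrays came from 2 slides, slide 1 with replicates 1 and 2 of both groups and slide 2 with replicate 3 of both groups. Infected replicate 3 stood furthest from the other arrays, with a mean correlation across features of 0.960 against 0.969 to 0.980 for the rest, and it dominated a first principal component that held 44.8% of the variance. The number of arrays, 3 per group, limited the precision.

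Infected lungs at day 3 had higher expression of Clca1 and Slc26a4, genes of mucus-producing epithelium, of the chemokines Ccl7 and Ccl11, and of Retnla. The largest change was in Clca1, which encodes a protein secreted by mucus-producing goblet cells and was 31.4-fold higher (95% interval 18.9 to 52.0; log2 6.43 ± 0.56 in uninfected and 11.40 ± 0.42 in infected lungs, SD, n = 3 each). Slc26a4, the epithelial anion exchanger pendrin, was 11.4-fold higher. Retnla, a secreted protein counted here among genes of alternative macrophage activation, was 9.50-fold higher, though a homogenate does not show which cells made it. Ccl7, a chemoattractant for monocytes, was 13.1-fold higher. The eotaxin Ccl11, which attracts eosinophils, was 7.97-fold higher.

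Altogether 19 of 15713 features passed an adjusted p of 0.05 in limma's moderated test, all 19 of them higher in infected lungs, by 2.63- to 31.4-fold. For each of the 19, all 3 infected values lay above all 3 uninfected values. Over all features, 1328 (8.45%) had groups that did not overlap, against 10% by chance. At an unadjusted p under 0.05 there were 525 features, 354 higher and 171 lower. With replicate number as a block 29 features passed, among them 18 of the 19, Rgs16 being lost at adjusted p = 0.0514. With slide as a block, chosen after seeing the data, 32 features passed, among them all 19. The size of many changes depended on the handling of background and on the normalisation. Clca1 had a log2 change of 4.97, against 4.21 with normexp fitted on the signals, 4.11 without background correction and 4.04 with the deposited value table. That table has neither background correction nor quantile normalisation, so its values do not separate the 2 steps. In it Ccl7 had 2.62, Saa3 2.01, Hmox1 2.11, Scin 1.71 and Fxyd4 1.04. Aldh1a3, Ccl24, Rnase2a and Ccl2 had 1.78, 1.43, 1.38 and 1.12 there, below the bounds given for them here, which hold for the background-corrected values alone. Retnla, Ccl11, Slc26a4, Timp1 and Selp moved by under 1.5 times in every alternative.

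Inflammatory cytokine and chemokine genes passed as higher with a preset correlation (camera, adjusted p = 1.08e-33) but not with an estimated one (adjusted p = 0.0797 with an estimated correlation). The list had a mean log2 change of 1.38 over 23 measured members, 1.13 on slide 1 and 1.87 on slide 2. Of these 23 genes 4 rose over all features tested, Ccl7, Saa3, Selp and Ccl2, none fell and 19 did not pass; adjusted over the list alone, 14 were higher. With replicate number as a block 8 of the 23 passed, the further 4 being Cxcl1 and Cxcl2 (both adjusted p = 0.0340), Sele (0.0341) and Osm (0.0187). Ccl7 had a log2 change of 3.71 ± 0.29 (SE; adjusted p = 0.00186). The acute-phase gene Saa3 rose by 3.03 ± 0.20 (adjusted p = 0.000795), from 5.82 ± 0.20 to 8.85 ± 0.13 (SD, n = 3 each). Ccl2, another monocyte chemoattractant, was not above background in any uninfected array and was at least 3.07-fold higher in infected lungs (adjusted p = 0.0212). Selp, the endothelial adhesion molecule P-selectin, was 6.10-fold higher (adjusted p = 0.0346), with log2 changes of 2.08 on slide 1 and 3.66 on slide 2. Il1b, a cytokine of early inflammation, had a log2 change of 1.43 ± 0.33 and did not pass (adjusted p = 0.533). The list's adjusted p was 1.61e-27 with slide as a block.

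**Figure D1:**
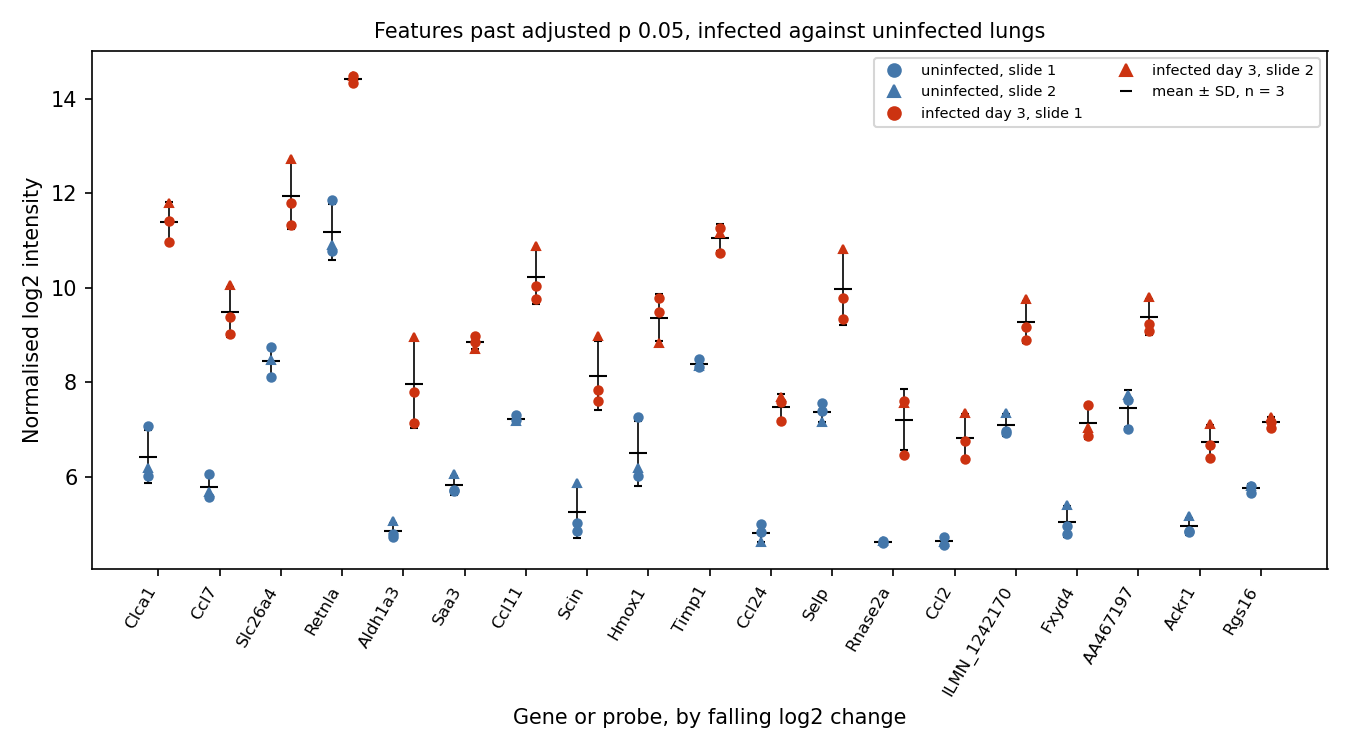
Normalised log2 intensity (vertical axis) of each of the 19 features past an adjusted p of 0.05 (horizontal axis, by falling log2 change) in 3 uninfected and 3 infected lungs. Points are single arrays, circles for slide 1 and triangles for slide 2, and bars are mean ± SD; for each feature the 3 infected points lie above the 3 uninfected points, and Clca1 shows the widest gap, from 6.43 to 11.40.

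Genes of mucus production rose as a group (adjusted p = 3.66e-19), with a mean log2 change of 1.62 over 8 measured members and closely similar means on slide 1 (1.56) and slide 2 (1.74). Clca1 (4.97 ± 0.32, adjusted p = 0.000795) and Slc26a4 (3.51 ± 0.35, adjusted p = 0.00563) rose, none fell and 6 did not pass; adjusted over the list alone, 6 of the 8 were higher. This was the 1 list of all 42 tested that passed with an estimated correlation (adjusted p = 0.0275) and in the directional fry test (adjusted p = 0.000658). With slide as a block its adjusted p was 9.64e-16. Markers of club and ciliated cells did not pass. Club cell markers had a mean log2 change of -0.09 over 9 genes (adjusted p = 0.557), with Scgb1a1, the main club cell secretory protein, at -0.20 ± 0.19 and Cyp2a5 at -0.34 ± 0.32. Ciliated cell markers averaged -0.18 over 16 genes (adjusted p = 0.0602), with Sntn at -0.50 ± 0.28 and Rsph9 at -0.33 ± 0.29. The ciliated list passed as lower with replicate number as a block (adjusted p = 0.0367) and with slide as a block (adjusted p = 0.0309), but not with an estimated correlation (adjusted p = 0.620), and its mean was -0.07 on slide 1 and -0.39 on slide 2. It passed in 12 of 23 alternatives, which leave out fry and the estimated correlation, and its mean over them ran from -0.33 to 0.02. Infected replicate 3 carried most of the decrease. The mean differences from the uninfected mean were -0.09, 0.13 and -0.57 in infected replicates 1, 2 and 3.

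Genes of alternative macrophage activation and type-2 effector function passed as higher (adjusted p = 1.16e-18) with a preset correlation only (adjusted p = 0.0797 with an estimated correlation). The list had a mean log2 change of 0.99 over 15 measured members, 0.78 on slide 1 and 1.41 on slide 2. Retnla (3.25 ± 0.29, adjusted p = 0.00342) and the eotaxin Ccl24 (at least 4.85-fold, adjusted p = 0.00203, not above background in uninfected lungs) rose, none fell and 13 did not pass; adjusted over the list alone, 6 were higher. Ccl17 passed as well with replicate number as a block (adjusted p = 0.00711). All 15 members had positive changes. Retnla was already bright in uninfected lungs, at a log2 intensity of 11.18 ± 0.59, and reached 14.43 ± 0.09 in infected lungs (SD, n = 3 each). Arg1, the arginase of such macrophages, had a log2 change of 1.34 ± 0.50 (adjusted p = 1.0), with 0.69 on slide 1 and 2.63 on slide 2, and the chitinase-like gene Chil3 had 0.54 ± 0.28 (adjusted p = 1.0). Fitted with slide as a block, the list had adjusted p = 1.37e-15.

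Type-2 cytokines, alarmins and their receptors passed as higher (adjusted p = 0.00146; adjusted p = 0.257 with an estimated correlation), with a mean log2 change of 0.50 over 11 measured genes and positive changes in 7 of them. Ccl11 rose (2.99 ± 0.29, adjusted p = 0.00498; 2.64 on slide 1 and 3.70 on slide 2), none fell and 10 did not pass; adjusted over the list alone, 3 were higher. Il33, an alarmin released by epithelial cells, had a log2 change of 1.09 ± 0.22 (adjusted p = 0.283). Il5, the eosinophil growth factor, was not above background in any uninfected array. Its difference is a bound of at least 1.76-fold and did not pass (adjusted p = 0.738). Il4 had 0.37 ± 0.33 and Il13 had -0.36 ± 0.37, both at adjusted p = 1.0. The list mean was 0.35 on slide 1 and 0.82 on slide 2, its adjusted p was 0.00950 with slide as a block, and without infected replicate 3 the mean was 0.32 (adjusted p = 0.0788).

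Eosinophil markers passed as higher (adjusted p = 8.94e-09; adjusted p = 0.0797 with an estimated correlation), with a mean log2 change of 0.90 over 7 measured genes, 0.66 on slide 1 and 1.37 on slide 2. Rnase2a, an eosinophil-associated ribonuclease also called Ear11, rose at least 4.0-fold from below background (adjusted p = 0.0212), and the related Ear6 was at least 1.92-fold higher without passing (adjusted p = 0.217; 0.0492 with slide as a block). None fell and 6 did not pass; adjusted over the list alone, 4 were higher. With slide as a block the list's adjusted p was 4.50e-07. Epx, Prg3, Siglecf and Hrh4 of this list lay under the detection filter. Alox15 is also a member of the type-2 effector list and Ccr3 of the type-2 cytokine list. The passing list therefore does not by itself show more eosinophils.

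Neutrophil markers passed as higher (adjusted p = 0.00352; adjusted p = 0.235 with an estimated correlation), but 0 of 11 genes passed alone. Their mean was 0.27, and members lay on both sides of 0: S100a8 had -0.37 ± 0.39 and S100a9 -0.26 ± 0.48, while Lcn2 had 0.72 ± 0.19 and Retnlg had 0.80 ± 0.25. Alveolar macrophage markers passed with a mean of 0.24 over 12 genes (adjusted p = 0.00312; adjusted p = 0.178 with an estimated correlation), with Marco at 0.67 ± 0.28 and Ctsk at 0.65 ± 0.23 and 0 passing alone. The 2 lists had adjusted p = 0.00950 and 0.00417 with slide as a block, and lost their calls without uninfected replicate 3 (0.0576 and 0.0671) and without infected replicate 1 (0.0948 and 0.0622). The neutrophil mean was 0.17 in each of these 2 fits. Neutrophil means were 0.22 on slide 1 and 0.38 on slide 2, and alveolar macrophage means 0.21 and 0.28. Monocyte and interstitial macrophage markers (mean 0.13, adjusted p = 0.0602), dendritic cell markers (0.21, adjusted p = 0.0554), plasma cell markers (0.28, adjusted p = 0.0766), B cell markers (-0.09, adjusted p = 0.499), NK cell markers (-0.17, adjusted p = 0.217) and mast cell and basophil markers (0.07, adjusted p = 0.464) did not pass. The monocyte list passed as higher in 14 of 23 alternatives and the dendritic cell list in 11 of 23, with adjusted p = 0.236 and adjusted p = 0.501 with an estimated correlation, which is not among the 23. The B cell list passed as lower in 3 of 23 alternatives, among them slide 1 alone (camera, adjusted p = 0.0306), and the plasma cell list as higher in 3 of 23. B cell means were -0.28 on slide 1 and 0.28 on slide 2, and plasma cell means 0.00 and 0.83. Among their members, Cd14 had 0.97 ± 0.21, Fcgr2b 0.82 ± 0.23, Batf3 0.82 ± 0.22, Cd83 0.88 ± 0.26, Xbp1 0.36 ± 0.25, Sdc1 0.35 ± 0.25, Blk -0.48 ± 0.26, Fcmr -0.43 ± 0.25, Il2rb 0.39 ± 0.19, Klrb1c -0.40 ± 0.20, Cma1 0.33 ± 0.22 and Gata2 -0.19 ± 0.21. T cell markers had a mean of -0.02 and a median of -0.06 over 14 genes against an upward test direction (adjusted p = 0.993). Cd3e had 0.09 ± 0.23, Ctla4 0.52 ± 0.22 and Cd3d -0.37 ± 0.22.

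T helper 1 and interferon-gamma response genes did not pass (mean 0.15 over 16 genes, adjusted p = 0.434). Cxcl10, an interferon-induced chemokine, had the largest change in this list, 2.22 ± 0.42, with an adjusted p of 0.219 over all features; it was the 1 member higher when adjusted over the list alone. Cxcl9 had 1.08 ± 0.45 and Il12a -0.55 ± 0.20, and both probes of Ifng lay under the detection filter. Type I interferon-stimulated genes passed as higher (mean 0.18 over 18 genes, adjusted p = 0.0104), with 0 members passing alone and with Rsad2 at 0.59 ± 0.32 and Ddx58 at 0.55 ± 0.27. Their adjusted p was 0.397 with an estimated correlation and 0.00950 with slide as a block. The mean was 0.05 on slide 1 and 0.44 on slide 2, and its highest adjusted p on leaving out 1 sample was 0.439, without infected replicate 3 (mean 0.06); without infected replicate 2 the mean was 0.28.

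Timp1, an inhibitor of matrix metalloproteinases, rose 6.36-fold (2.67 ± 0.21, adjusted p = 0.00187). It was the 1 of 27 measured extracellular matrix and wound healing genes that passed, over all features and adjusted over the list alone; 26 did not pass and none fell. Thbs1, a matrix glycoprotein, had 1.63 ± 0.43 (adjusted p = 0.836), with 0.84 on slide 1 and 3.19 on slide 2. The list passed as higher with a mean of 0.26 and a median of 0.03 (adjusted p = 0.00532), 0.18 on slide 1 and 0.41 on slide 2. Its adjusted p was 0.329 with an estimated correlation, 0.0107 with slide as a block and at most 0.105 on leaving out 1 sample (infected replicate 3). Coagulation genes passed (mean 0.16 over 14 genes, adjusted p = 0.0193; adjusted p = 0.192 with an estimated correlation), with 0 genes passing alone over all features and 1 adjusted over the list alone; F10, coagulation factor X, had 0.91 ± 0.20 (adjusted p = 0.372) and F2rl2 had 0.46 ± 0.25. Complement and acute phase genes also passed (mean 0.15 over 16 genes, adjusted p = 0.0243; adjusted p = 0.192 with an estimated correlation), with 0 genes passing alone and with C1s1, a complement protease, at 0.57 ± 0.25. They had adjusted p of 0.0309 and 0.0290 with slide as a block. Coagulation means were 0.09 on slide 1 and 0.30 on slide 2, and complement means 0.17 and 0.12. On leaving out 1 sample their adjusted p was at most 0.178 (coagulation, mean 0.09 without infected replicate 3) and 0.157 (complement, without infected replicate 1).

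Cell cycle genes passed as higher by a small amount (mean 0.19 over 23 genes, 20 of them positive, adjusted p = 0.000329; adjusted p = 0.0797 with an estimated correlation), with 0 passing alone. Top2a, a topoisomerase of dividing cells, had 0.63 ± 0.20 and Cdk1 had 0.37 ± 0.22. The list mean was 0.17 on slide 1 and 0.23 on slide 2, and its adjusted p was 0.000191 with slide as a block. Hmox1, the haem-degrading enzyme, rose 7.32-fold (2.87 ± 0.37, adjusted p = 0.0307; 2.99 on slide 1 and 2.63 on slide 2). The other 20 oxidative stress genes did not pass, and the list did not either (mean 0.17, adjusted p = 0.119). The list passed as higher in 3 of 23 alternatives, over which its mean ran from 0.03 to 0.31. Mt2, a metallothionein, was not above background in any uninfected array, and its difference is a bound of at least 1.66-fold (adjusted p = 0.601). Genes of MHC class II presentation (mean 0.05 over 14 genes, adjusted p = 0.620) and of cholesterol synthesis (mean -0.10 over 13 genes, adjusted p = 0.354) did not pass, with H2-Oa at -0.55 ± 0.25, Cd80 at 0.92 ± 0.42, Stard4 at -0.40 ± 0.23 and Idi1 at -0.55 ± 0.39. Cholesterol synthesis means were -0.22 on slide 1 and 0.14 on slide 2. The list passed as lower in 3 of 23 alternatives, among them slide 1 alone (camera, adjusted p = 0.0306).

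Among the remaining features past the threshold, Aldh1a3, a retinaldehyde dehydrogenase, was at least 6.76-fold higher (adjusted p = 0.0307) and Scin, an actin-severing protein, was 7.45-fold higher (adjusted p = 0.0355; above background in 1 of 3 uninfected arrays). Fxyd4, a regulator of the sodium pump, was 4.24-fold higher (adjusted p = 0.0222; above background in 1 of 3 uninfected arrays). The last 4 fell outside the rule for named genes and were named after their values were seen. They were Ackr1, an atypical chemokine receptor, at least 2.88-fold higher (adjusted p = 0.0346), AA467197, 3.81-fold (adjusted p = 0.0480), Rgs16, 2.63-fold (adjusted p = 0.0346), and the probe ILMN_1242170, unnamed here, 4.55-fold (adjusted p = 0.0212). Cxcl1, Cxcl2, Sele, Osm and Ccl17 above also fell outside the rule. Those genes were named because they passed with replicate number as a block.

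No gene passed as lower in infected lungs (0 of 15713 in limma, with 171 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.281). Of the 10 named genes with the smallest p in this direction, the 8 above background in both groups had log2 changes of -0.67 to -0.96. Spon2, a secreted matrix protein, had -0.96 ± 0.22 (adjusted p = 0.508), Amer1 -0.71 ± 0.18 (0.724) and Sult1d1 -0.74 ± 0.19 (0.815). Zfp113 and Igf2bp1 were not above background in any infected array, so their differences are bounds of at least 1.18-fold (adjusted p = 0.527) and 1.58-fold (adjusted p = 0.794). Pon1, Phf24, Hoga1, Birc6 and Tdp1 had -0.85, -0.83, -0.74, -0.72 and -0.67, each at adjusted p = 1.0. Limma with array quality weights passed 5 features as lower, among them Spon2 and Igf2bp1, beside 57 higher; the plain two-sample test with Benjamini-Hochberg adjustment passed 0 in either direction.

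Structural cells of the lung showed no change that passed in the main fit. The mesothelial list passed as lower in 3 of 23 alternatives, over which its mean ran from -0.39 to -0.05. The endothelial list passed as lower in 2 of 23. Alveolar type 2 cell markers averaged 0.03 over 13 genes (adjusted p = 0.556), with the surfactant gene Sftpc at -0.04 ± 0.31, Sftpd at 0.16 ± 0.18 and Lamp3 at 0.43 ± 0.30. Alveolar type 1 cell markers averaged 0.03 over 12 genes (adjusted p = 0.649), with Clic5 at 0.39 ± 0.28 and Aqp5 at -0.25 ± 0.22. Endothelial markers averaged -0.11 over 21 genes (adjusted p = 0.181), with Cdh5 at -0.34 ± 0.19 and Sox17 at -0.34 ± 0.24. Fibroblast and smooth muscle markers averaged -0.09 (adjusted p = 0.310; Mfap5 -0.54 ± 0.21, Npnt -0.39 ± 0.27), and mesothelial markers -0.20 (adjusted p = 0.0996; Lrrn4 -0.54 ± 0.31, Gpm6a -0.40 ± 0.22). Platelet markers averaged 0.12 (adjusted p = 0.181), with Ppbp at 0.52 ± 0.31 and Clec1b at -0.58 ± 0.22. Erythroid markers passed as higher (mean 0.28 over 11 genes, adjusted p = 0.00532) with 0 passing alone; Alas2, the haem synthesis enzyme of red cell precursors, had 0.82 ± 0.34 and the red cell anion exchanger Slc4a1 had 0.80 ± 0.34. The erythroid list's adjusted p was 0.236 with an estimated correlation and 0.00950 with slide as a block, and its mean was 0.27 on slide 1 and 0.28 on slide 2. Without uninfected replicate 2 the mean was 0.14 (adjusted p = 0.158). The reference genes Actb and Gapdh had 0.12 ± 0.29 and -0.08 ± 0.24.

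**Figure D2:**
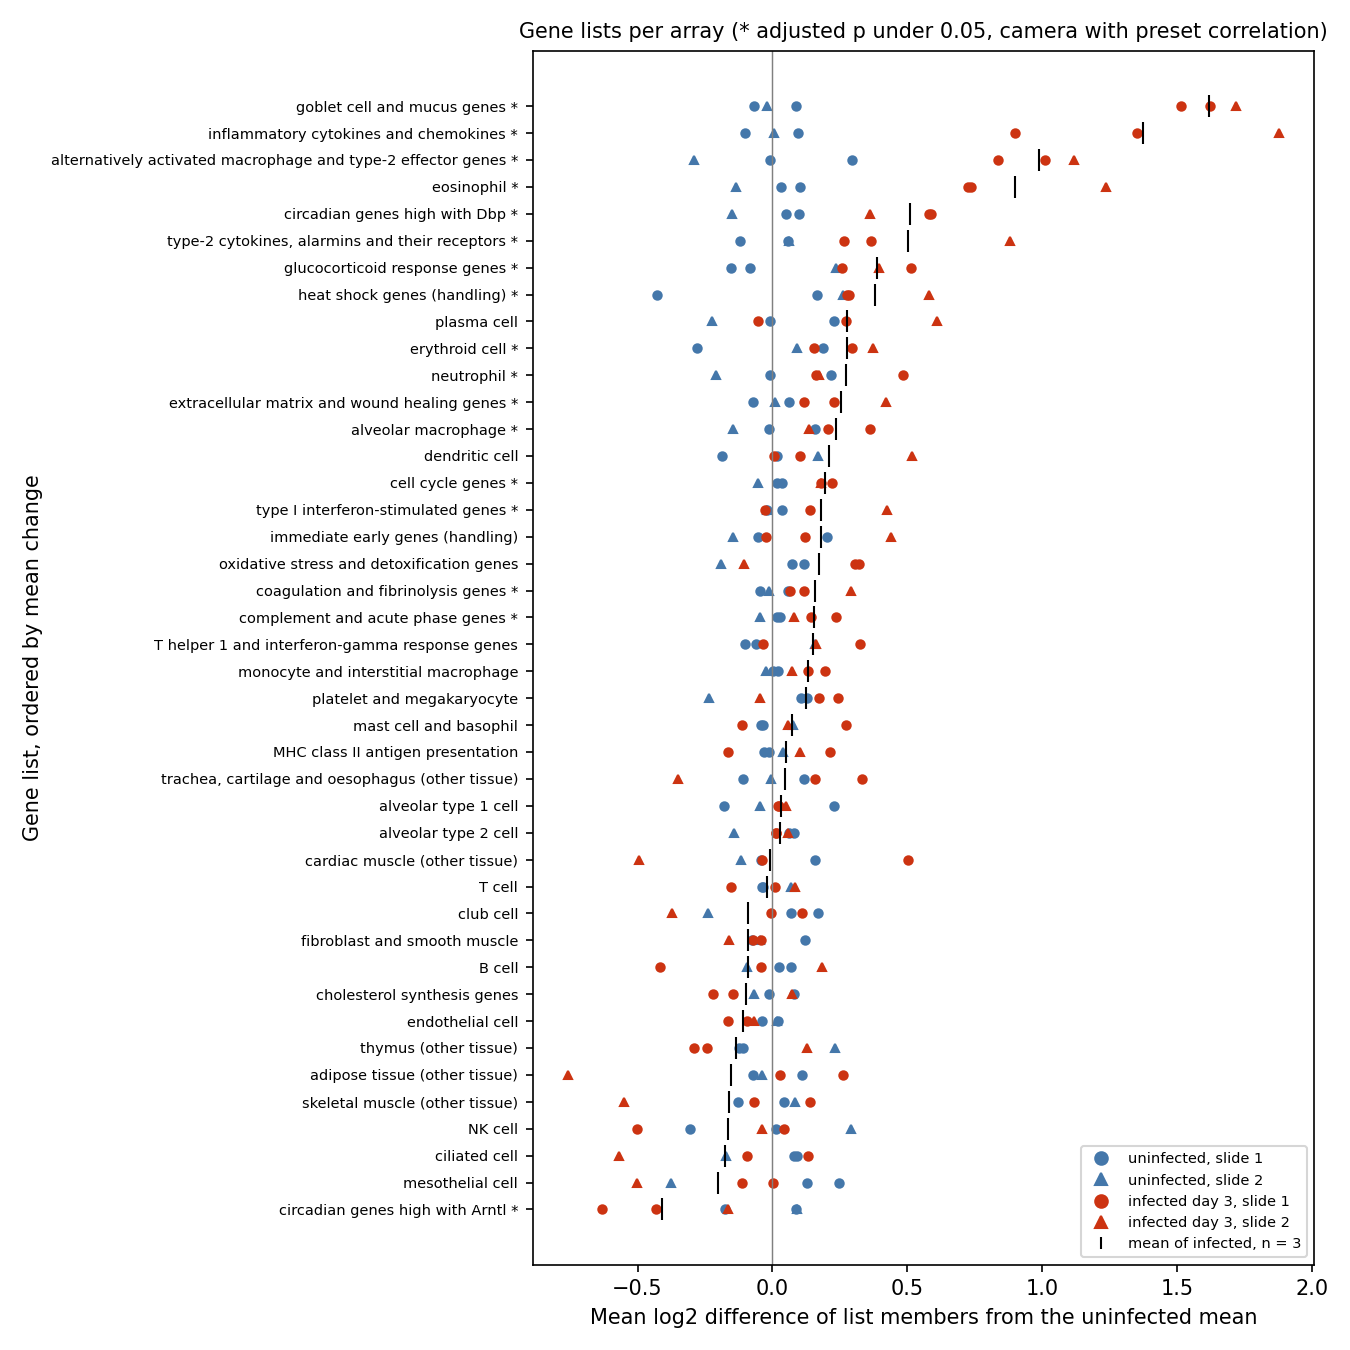
Mean log2 difference from the uninfected mean (horizontal axis) of the members of each of the 42 tested gene lists (vertical axis, ordered by mean change) in each array. Blue points are uninfected and red points infected lungs, circles slide 1 and triangles slide 2, the black bar is the mean of the 3 infected arrays, and a star marks lists past an adjusted p of 0.05 with a preset correlation; the goblet cell and mucus list shows the highest mean, 1.62, and the clock genes high with Arntl the lowest, -0.41.

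Clock genes that peak with Dbp passed as higher (mean 0.51 over 9 genes, all 9 positive, adjusted p = 1.75e-06; adjusted p = 0.0797 with an estimated correlation), with Per2, a core clock repressor, at 1.03 ± 0.28 and Dbp at 0.95 ± 0.27. Clock genes that peak with Arntl passed as lower (mean -0.41 over 3 genes, adjusted p = 0.0145; adjusted p = 0.257 with an estimated correlation), with Npas2 at -0.60 ± 0.19 and Arntl at -0.48 ± 0.26. Glucocorticoid response genes passed as higher (mean 0.39 over 15 genes, adjusted p = 1.45e-06; adjusted p = 0.178 with an estimated correlation), Lcn2 and Mt2 having the smallest p among them. Heat shock genes passed as higher as well (mean 0.38 over 13 genes, adjusted p = 0.00146; adjusted p = 0.184 with an estimated correlation), with Hspb1 at 0.65 ± 0.25 and Hspa8 at 0.44 ± 0.19. Over all features 0 members of these 4 lists passed; adjusted over the list alone, 2 genes that peak with Dbp and 2 glucocorticoid response genes were higher, 1 gene that peaks with Arntl was lower and 0 heat shock genes passed. With slide as a block the Dbp, Arntl, glucocorticoid and heat shock lists had adjusted p of 1.49e-06, 0.0186, 6.81e-06 and 0.000461. Means on slide 1 and slide 2 were 0.51 and 0.51 for the Dbp list, -0.49 and -0.26 for the Arntl list, 0.50 and 0.16 for the glucocorticoid list and 0.41 and 0.32 for the heat shock list. The Arntl list had an adjusted p of at most 0.147 on leaving out 1 sample (infected replicate 1), and the heat shock list had a mean of 0.17 (adjusted p = 0.0592) without uninfected replicate 2. Immediate early genes did not pass (mean 0.18, adjusted p = 0.0602; Atf3 1.19 ± 0.37, Egr2 0.83 ± 0.29). Their mean was -0.03 on slide 1 and 0.59 on slide 2, and they passed as higher in 2 of 23 alternatives, without uninfected replicate 1 (adjusted p = 0.00715) and without infected replicate 2.

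Markers of tissues that can be carried along in dissection did not pass with all samples. Skeletal muscle genes averaged -0.16 (adjusted p = 0.249; Atp2a1 -0.39 ± 0.24, Tnnt3 -0.35 ± 0.29), adipose genes -0.15 (adjusted p = 0.620; Cox8b -0.89 ± 0.64, Thrsp -0.59 ± 0.33) and thymus genes -0.14 (adjusted p = 0.431; Lef1 -0.44 ± 0.27, Cd8b1 -0.13 ± 0.21). Tracheal and oesophageal genes had a mean of 0.05 and a median of -0.02 (adjusted p = 0.677; Krt15 0.60 ± 0.35, Trp63 0.48 ± 0.23). Cardiac muscle genes had a mean of -0.01 and a median of -0.08 against an upward test direction (adjusted p = 0.799; Ankrd1 0.56 ± 0.19, Myh7 -0.30 ± 0.19). Means differed in sign between slide 1 and slide 2, at 0.17 and -0.38 for cardiac muscle, 0.08 and -0.63 for skeletal muscle, 0.13 and -0.72 for adipose and 0.24 and -0.34 for tracheal genes. The cardiac list passed as lower without infected replicate 2 (mean -0.27, adjusted p = 0.0283) and as higher without infected replicate 3 (mean 0.23, adjusted p = 0.00986).

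Precision rested on 3 mice per group. Leaving out uninfected replicate 1, 2 or 3 gave 8, 7 and 6 features past the threshold, and leaving out infected replicate 1, 2 or 3 gave 12, 25 and 19. Of the 19 called with all samples, 8, 7, 6, 11, 16 and 13 passed in these fits. Clca1, Saa3, Ccl7, Timp1, Ccl24 and Retnla passed in all 6 of these fits, Ccl11 and Slc26a4 in 4, and the probe ILMN_1242170 in 3. Hmox1, Selp, Ccl2, Aldh1a3, Scin and Rnase2a passed in 2 of 6, and Fxyd4 and Ackr1 in 1; Rgs16 and AA467197 passed in 0 of them.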

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

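The alternatives with slide as a block and with slide 1 alone were chosen after seeing the data. The count of features past the threshold, 19 higher and 0 lower, was 10 with normexp fitted on the signals, 10 without background correction, 10 with a neqc offset of 50, 11 with cyclic loess, 3 with the deposited value table, 4 with no filter on detection and 10 with detection on all 6 arrays, all higher. It was 29 with the replicate block and 32 with slide as a block, all higher, and 62 with array quality weights, 57 higher and 5 lower. The plain two-sample test passed 0 (564 at an unadjusted p under 0.05). Leaving out each sample gave 6 to 25, all higher. The filter on all 6 arrays left 12 of the 19 to be tested; for the other settings the cause was not tested. In each of these fits the 19 features, where tested, kept their positive direction. Their groups did not overlap, so fits to the same normalised values could not change that direction and are no test of it. Array weights were lowest for infected replicate 3 (0.225) and uninfected replicate 3 (0.352).

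Biological lists past the threshold numbered 9, against 1 with the estimated correlation, 1 in fry and 5 to 10 leaving out each sample. On slide 1 alone the type-2 cytokine, type I interferon, matrix and coagulation lists did not pass (camera, adjusted p = 0.141, 0.512, 0.103 and 0.378). Cholesterol synthesis genes passed there as lower (camera, adjusted p = 0.0306). Technical lists numbered 4, against 0 with the estimated correlation, 0 in fry and 3 to 6 leaving out each sample. Cell type lists numbered 4, against 7 with neqc offset 50, 8 with 75th percentile scaling, 9 with the deposited value table, 7 with detection on all 6 arrays, 8 with all probes separately, 7 with trend and robust, 7 with array weights, 0 with the estimated correlation, 0 in fry and 3 to 8 leaving out each sample. The test direction of the cardiac muscle list, not past the threshold with a mean of -0.01, turned without infected replicate 2, where it passed as lower with a mean of -0.27 (adjusted p = 0.0283), and it passed as higher without infected replicate 3, with a mean of 0.23 (adjusted p = 0.00986), and the cause was not tested.

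Of the 17 lists, 7 passed in all 6 fits that left out a sample. Over all alternatives, named genes kept their side of the threshold in 2359 results, fell short in 99, passed newly in 12 and reversed in 0. Lists did so in 925, 61, 62 and 1. A change of direction counted as reversed only where the main fit or the alternative passed. Results short of the threshold in both could therefore change direction and still count as kept, as the immediate early list did on slide 1 alone. Among lists and genes named by the fixed rule, the replicate block changed the call of the ciliated list alone. Outside that rule it ended the call of Rgs16 and added 11 features. Lists have no value under the plain two-sample test. Signal over background limits Ccl2, Ccl24, Rnase2a, Aldh1a3 and Ackr1, whose folds are bounds.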

Other observations

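The tests of slide, airway tissue, macrophages, collection time and glucocorticoids below were chosen only after the results were seen, and so were the genes named in the first 2 paragraphs.

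With slide as a block 13 features passed, all higher, that had not passed without it. The neutrophil chemoattractants Cxcl1 (log2 change 2.57, adjusted p = 0.0383) and Cxcl2 (at least 3.59-fold from below background, adjusted p = 0.0300) and the endothelial adhesion molecule Sele (2.36, adjusted p = 0.0372) were among them. So were Ccl17 (2.33, adjusted p = 0.00346), a chemokine for CCR4-bearing T cells, and Ch25h (2.52, adjusted p = 0.0323), which makes 25-hydroxycholesterol. Foxa3, a transcription factor of goblet cells, had 1.35 (adjusted p = 0.0284), and Sox9 had 1.63 (adjusted p = 0.0180). The others were Pla2g4c, Serpina3f, Adamts4, Ear6, Alox12e and the probe ILMN_2725927. Without the block the adjusted p of the 13 ran from 0.0554, as for Cxcl1 and Ch25h, to 0.815 for Sox9.

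Ccl2, Ccl7, Ccl11, Ccl12 and Ccl8 lie next to each other on mouse chromosome 11 in the GRCm38.p6 gene order. The first 3 rose, Ccl7 by 3.71 and Ccl11 by 2.99 on the log2 scale and Ccl2 by at least 3.07-fold, since it was not above background in uninfected lungs. Ccl12 had 1.07 ± 0.28 (SE; adjusted p = 0.803) and Ccl8 had 0.08 ± 0.36 (adjusted p = 1.0); whether these changes differ from each other was not tested. Among the 19 features past the threshold, 16 had a larger fitted change on slide 2 than on slide 1, with medians of 2.92 and 2.59.

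There are 10 splits of the 6 samples into 3 and 3, too few for a share under 0.05. The real split gave 19 features, all higher, as 1 of 10 splits with that many, and the other splits gave at most 0; for lower features 10 of 10 splits gave 0 or more. Biological lists numbered 9 against at most 5 in the others (1 of 10 as large), technical lists 4 against at most 3 (1 of 10), and cell type lists 4 against up to 5 (4 of 10). Whether the replicate numbers pair the samples is not known. If they do, the highest among the 3 other splits that part all 3 pairs were 0 features and 4, 3 and 5 lists.

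Slide is unlikely to account for the 19 higher features, since each slide held equal numbers of both groups. A shift shared by all arrays of a slide cancels from the group difference. Slide as a block left the log2 changes as they were, so the 19 of 19 that passed there are no further test. On slide 1 alone 13 of the 19 passed. What stays open is anything that differed between the infected and uninfected mice on both slides, such as handling; infection itself is the difference the design names.

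A larger share of airway tissue in the infected samples could raise mucus genes such as Clca1. It would raise club and ciliated markers too, but their median change over 25 genes was -0.15 (SD 0.19), against a median of 0.73 for the goblet list with a bound for Muc5ac, and the largest was Dnah5 at 0.38. More macrophages could raise Retnla and Ccl24. In 29 macrophage and monocyte markers the median change was 0.11 (SD 0.31), with Cd14 highest at 0.97, against 3.25 for Retnla and at least 2.28 for Ccl24. These genes were compared because they had passed, so a gap was built in by that choice. Over all 15 measured members of their list the median was 0.61. The club and ciliated values argue against a larger share of airway tissue as the whole cause of the higher mucus list. The macrophage comparison cannot decide, and a larger share of macrophages stays open. More goblet cells, more eosinophils and a change of expression within resident cells were not tested and stay open.

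Clock genes that peak with Dbp passed as higher and those that peak with Arntl as lower with a preset correlation only (adjusted p = 0.0797 and adjusted p = 0.257 with an estimated correlation), 0 members passed alone, and the Arntl list passed in 3 of 6 fits that left out a sample. The Dbp minus Arntl difference was 0.92 higher in infected lungs on the log2 scale, which restates the shift of the same lists and so does not test collection time. A glucocorticoid response may contribute, since 12 of 14 glucocorticoid response genes outside the clock lists had positive changes, with a mean of 0.38 (SE over genes 0.09). That SE takes the genes as independent, though the estimated correlation of the glucocorticoid list was 0.14. Lcn2 also belongs to the acute phase and neutrophil lists, so the shift is not specific to glucocorticoids. The whole glucocorticoid list, however, had adjusted p = 0.178 with an estimated correlation, 0 members passing alone and means of 0.50 on slide 1 and 0.16 on slide 2. Collection time is not given in the sources used here, so these explanations and an effect of infection on the clock cannot be told apart.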
